A study of Mus musculus with 2 samples.

How the data were processed

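Cells of day 9 differentiations of the MM13 mouse embryonic stem cell line under RA or RA+BMP4 were dissociated in cold trypsin, depleted of dead cells with a kit and captured with the 10x Genomics Chromium platform, per the labels' protocols. The deposited values were raw UMI counts per gene and barcode, written by software version 3.0.2 per the file headers, and the submitters' processing notes name Cell Ranger 3.0.2, CASAVA and the GRCm38 build. The annotation release and the settings of cell calling are not given in the sources used here. The lowest barcode totals were 500 and 602 UMIs. Both feature lists held the same 31053 genes. Coordinates came from the GENCODE vM21 annotation of the same build, matched by gene ID, and all 442 named or listed genes had a match.

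Each condition had 1 library, so the design allowed no test between conditions. No p-value was computed, and no error between replicates could be estimated. The planned comparisons, gene lists, cell type markers and naming limits for genes were fixed before the data were examined, and later additions are named as such. Cells needed at least 1000 genes and at most 10% mitochondrial UMIs, which left 6038 RA and 8650 RA+BMP4 cells. Scrublet, run per library in scanpy 1.11.5 on all barcodes with at least 1000 genes and an expected rate of 8%, called 138 (2.29%) and 300 (3.47%) of the passing cells as doublets, and they were removed. Called doublets had median depths of 28298 and 20942 UMIs. The pluripotent-like cells were deeper still, with a median doublet score of 0.0717 against 0.0303 in neuron-like cells, and the 59 endoderm-like cells had the highest, 0.126, so doublets in these 2 classes are not excluded.

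Both libraries were clustered together without integration. Counts were scaled to 10000 per cell and log-transformed, 3000 variable genes were chosen, and 30 principal components, 20 nearest neighbours and Leiden clustering (leidenalg 0.10.2) at a resolution of 1 gave 23 clusters. All 32 cell type marker lists, all gene lists, and mitochondrial and ribosomal genes were left out of the clustering genes, so that class names rest on genes not used to form the clusters. A cluster took the name of the class with most markers among its 10 leading genes by fold over all other clusters, with 5 CPM added to both sides, provided at least 3 markers were found in 10% of its cells at 1.5-fold the level of other cells. Ties, also at 0 leading markers, went to the class with the highest mean log2 fold of its markers, which named clusters 3, 12 and 13 roof plate-like with no marker among their leading genes. A cluster stayed unnamed where another group that met the same condition had as many leading markers, or where its cells' depth was under 1/3 of their library's median with no leading marker of a class that met it. Cluster 15 was named mesenchyme-like because the class with more leading markers did not meet the condition, and cluster 20 was left unnamed because dI1 did not. The markers were fixed in advance, but this scoring rule was written after the clusters were seen and was adjusted once, when the Foxd3-led cluster 4 at first came out unnamed. Progenitor lists were pooled as progenitor-like and neuron lists as neuron-like.

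Shares were given with exact Clopper-Pearson intervals, and a share of 0 with the share that 3 cells would give. Counts were summed over cells per library and scaled to CPM, and the ratio RA+BMP4 over RA was given with an exact conditional binomial interval. Genes were called apart at a CPM of at least 20 in 1 library and a ratio of at least 2 in either direction. A library with fewer than 3 counts of a gene was set to 3 counts in the ratio. Genes named in the text are members of the fixed lists and markers, the 10 highest and 10 lowest ratios of the whole libraries and the 6 highest and 6 lowest within each class, leaving out predicted gene models and mitochondrial genes. Leading genes of clusters serve only to identify them. The values of some listed genes are not reported here. The roof plate-like comparison was added after the data were seen.

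The gene lists were BMP response, BMP ligands and inhibitors, Wnt targets, Wnt ligands and R-spondins, Notch pathway, retinoic acid pathway, Hox paralog groups 1 to 5, 6 to 8 and 9 to 13, S phase, G2 and M phase, glutamatergic, GABAergic and glycinergic, neuropeptides, commissural axon guidance, dissociation and heat stress, hypoxia and glycolysis, p53 response, cholesterol synthesis and cytosolic ribosomal proteins. Members needed a CPM of at least 1. A list's median log2 ratio was placed among 10000 random lists of the same size, each member drawn from the 200 genes nearest in mean expression. Prrxl1 stood in for Drgx, its newer symbol, and Hoxd4 and Aldoa had no unique symbol in the feature lists. Shares of cells with a UMI were taken after thinning each cell to 5000 UMIs without replacement.

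The steps were tested on simulated data. Poisson counts were drawn from the pooled means of the real libraries, with 200 genes of at least 40 CPM changed, 50 per fold. All genes changed 3-fold up, 3-fold down or 8-fold were recovered (100%) in the whole library (6924 genes), progenitor-like (6495) and neuron-like (6796) steps, and 0% of 1.5-fold or unchanged genes were called. The intervals held the true ratio for 88% to 100% of the genes of a fold. These simulations hold counting error alone and no spread between cultures. Of 200 random lists of 10 genes, 7% lay outside the middle 95%, and all lists raised by 0.8 log2 lay above it (13910 genes). Cells were also simulated from all 23 clusters, each drawn from its cluster's summed profile with no spread between cells of a cluster beyond counting. Separation was thus built in, and the adjusted Rand index of 1 does not show how well real cells separate. In this simulation 91.9% of cells received the same cell group and 86.5% the same class name as in the real data. Clusters 19, 20 and 21, unnamed in the real data, took a name there, cluster 15 lost its name and cluster 7 took another progenitor name. An earlier simulation of 6 clusters, drawn in the same way, also separated them fully. It named only 66.7% of cells alike, since a name rests on the ratio to the other cells present. With progenitor and newborn cells absent, the roof plate-like cluster 0 was named as progenitor and the dI2-like cluster 4 as newborn neuron.

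Alternatives covered TMM factors (edgeR 4.0.16 in R 4.3.3), median-of-ratios scaling, equal weight per cell, other limits on CPM and ratio, other cell filters, doublets kept, other clustering resolutions, markers kept among the clustering genes, each library clustered alone, random lists without matching, and other thinning. A count of genes or lists was taken as the same within 1.5-fold, a ratio of shares within its 95% normal interval on the log scale, a named gene within its exact interval, and a list median within a bootstrap interval (2000 draws). Further alternatives, without the pluripotent-like cells, without the 3 unnamed clusters, and equal weight per cell for the gene lists, were added after the data were seen. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.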

Results

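Single-cell RNA sequencing was performed on day 9 of a differentiation of MM13 mouse embryonic stem cells, a line grown here toward neurons of the dorsal spinal cord. One culture received retinoic acid (RA), a signal that gives neural cells a caudal identity. The other received RA and bone morphogenetic protein 4 (RA+BMP4), a member of the ligand family that roof plate and surface ectoderm release beside the dorsal neural tube. Each condition was represented by 1 library, so no replicate error could be measured, no difference was tested, and each value describes these 2 libraries. The RA file held 9704 barcodes and 122110565 unique molecular identifiers (UMIs), and the RA+BMP4 file held 13121 barcodes and 115268932 UMIs. After the cell filter and removal of called doublets, 5900 RA cells (60.8% of barcodes) and 8350 RA+BMP4 cells (63.6%) were kept. Kept RA cells had a median of 14196 UMIs and a mitochondrial share of 6.06%, against 10465 UMIs and 4.22% in RA+BMP4. Intervals in brackets are 95% intervals, exact Clopper-Pearson for shares of cells and exact conditional binomial for ratios of counts, and cover counting error only. Intervals of ratios of shares and of gains in list UMIs per cell are normal approximations. Those over resampled cells or genes are bootstrap intervals.

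The first comparison asked which cell classes the 2 libraries held. The RA+BMP4 library held more dI1-like, dI2-like and roof plate-like cells, and the RA library held more progenitor-like, dI4/dILA-like and dI5/dILB-like cells. Neurons resembling dI1, the Atoh1-lineage commissural and proprioceptive relay class, made up 2.97% of RA cells [2.55 to 3.43] and 21.1% of RA+BMP4 cells [20.2 to 21.9]. Those resembling dI2 made up 2.53% [2.14 to 2.96] and 8.17% [7.59 to 8.78]. The dI5/dILB-like class, which takes its name from excitatory neurons that relay pain and touch, made up 19.2% of RA cells [18.2 to 20.2] and 2.02% of RA+BMP4 cells [1.73 to 2.35].

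The dI4/dILA-like class, named for inhibitory dorsal horn neurons, made up 11.5% of RA cells and 3.58% of RA+BMP4 cells, or 677 and 299 cells. Among neuron-like cells alone, dI1-like cells were 6.07% in RA and 51.3% in RA+BMP4, and dI5/dILB-like cells were 39.2% and 4.94%. All neuron-like cells together made up 48.9% of RA cells [47.6 to 50.1] and 41.0% of RA+BMP4 cells [39.9 to 42.1], a ratio of 0.839. That ratio was 1.10 when cells needed at most 5% mitochondrial UMIs and at least 2000 genes, so its direction rests on the cell filter. The same stricter filter gave a dI1-like ratio of 16.6 in place of 7.10 and a dI2-like ratio of 5.25 in place of 3.23. It kept only 1247 RA cells beside 5894 RA+BMP4 cells, with 15 RA cells in either class. The intervals of these ratios were therefore wide, 10.0 to 27.5 for dI1-like and 3.14 to 8.76 for dI2-like cells. The dI2-like ratio was 1.77 when each library was clustered alone.

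Progenitor-like cells made up 16.5% of the RA library [15.5 to 17.4] and 4.53% of the RA+BMP4 library [4.09 to 4.99], a ratio of 0.275 that was 0.529 at a clustering resolution of 1.5. Roof plate-like cells, named for the dorsal midline source of BMP and Wnt ligands, made up 18.1% [17.1 to 19.1] and 34.8% [33.7 to 35.8]. Different clusters held the largest part of the roof plate-like class in the 2 libraries. Cluster 0, led by Pla2g7, Rspo3 and Wnt1, held 232 RA and 1856 RA+BMP4 cells, and cluster 3, led by Cp and Colec12, held 534 and 297. Clusters 12 and 13, also roof plate-like, were led by mitotic genes such as Cenpf and by histone genes such as Hist1h1b, and held 135 and 167 RA and 410 and 340 RA+BMP4 cells. No roof plate marker was among the 10 leading genes of clusters 3, 12 and 13. Their name rests on markers such as Msx1, at 483, 443 and 411 CPM against 126, 137 and 137 in the other clusters. Msx1 was also a marker of Atoh1-type progenitors in the fixed lists. Lmx1a had 53.8, 42.9 and 48.3 CPM against 13.8, 15.3 and 14.9. Gdf7 had only 0.885, 1.67 and 1.84 against 0.836, 0.799 and 0.785, and Msx2 in cluster 3 had 9.94 against 10.9. Dorsal progenitors among these cells were not excluded, so the roof plate-like and progenitor-like shares, and their ratios between the libraries, depend on these names. In RA+BMP4, the dorsal progenitor gene Olig3 was found in a larger share of cells, given below, than the whole progenitor-like class. Cells with Olig3 therefore also lay outside that class, and which clusters held them is not given here. Progenitor-like clusters 7 and 11 held 550 and 421 RA cells and 220 and 158 RA+BMP4 cells.

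Most dI1-like cells of the RA+BMP4 library lay in 2 clusters. Cluster 5, led by Barhl2 and Lhx2, held 80 RA and 718 RA+BMP4 cells, and cluster 6, led by Sorcs3, Kctd4 and Robo2, held 13 and 774. Another dI1-like cluster, 17, was led by Atoh1, which specifies dI1 progenitors, and held 82 and 266 cells. Cluster 6 came almost entirely from the RA+BMP4 library. When that library was clustered alone, 712 of the 774 cells fell in a cluster, apart from most of cluster 5, that was named pan-neuronal-like rather than dI1-like, and the dI1-like ratio was 5.11. The dI2-like class was cluster 4, led by Foxd3. The dI5/dILB-like class consisted of clusters 2 and 16, the latter led by Tlx1 and Lmx1b, and the dI4/dILA-like class of clusters 9 and 18. At a clustering resolution of 1.5, other class names appeared, V1-like with 0.932% of RA and 3.17% of RA+BMP4 cells, and dI6-like with 7.12% and 0.778%. The V1-like class held 55 and 265 cells, while the dI2-like class held 94 and 420 in place of 149 and 682. Foxd3 is a fixed marker of both, so the V1-like name may cover cells otherwise named dI2-like. The dI6-like class held 420 RA cells, while pan-neuronal-like and dI4/dILA-like RA cells numbered 179 and 551 in place of 471 and 677. Which cells changed name was not traced. With each library clustered alone, 361 RA cells and no RA+BMP4 cluster were named dI6-like, and no cluster V1-like.

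Newborn neuron-like cells, led by Neurog2 and Neurod4, made up 4.75% of RA and 3.74% of RA+BMP4 cells, and pan-neuronal-like cells with no subtype name 7.98% and 2.44%. Both directions reversed when each library was clustered alone, to 5.75% and 7.49% for newborn neuron-like and 3.47% and 15.3% for pan-neuronal-like cells. The newborn neuron-like ratio of 0.787 was also 0.400 without a cell filter and 0.933 under the stricter one, so neither class is read as different between the libraries. Pluripotent-like cells, led by Dppa5a, L1td1 and Zfp42, made up 5.51% of RA cells [4.94 to 6.12] and 1.98% of RA+BMP4 cells [1.69 to 2.30]. Their median depths of 54182 and 39195 UMIs gave them 16.8% and 6.53% of all UMIs. Endoderm-like cells made up 0.458% and 0.383%, a ratio of 0.837 whose interval, 0.502 to 1.40, holds 1. Mesenchyme-like cells were not compared as a class, because cluster 15 carried more leading markers of another class, one with too few markers found to give a name. Cluster 1, led by Col1a2 and Col1a1, held 4.97% of RA and 7.50% of RA+BMP4 cells, and cluster 15 held 2.42% and 3.57%. Clusters 19, 20 and 21 stayed unnamed, at 2.20%, 0.983% and 0.0339% of RA cells and 2.08%, 2.73% and 1.46% of RA+BMP4 cells. Cluster 19 was shallow and led by muscle genes such as Actc1, and cluster 20 was shallow with Barhl2 and Barhl1 among its leading genes.

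**Figure D1:**
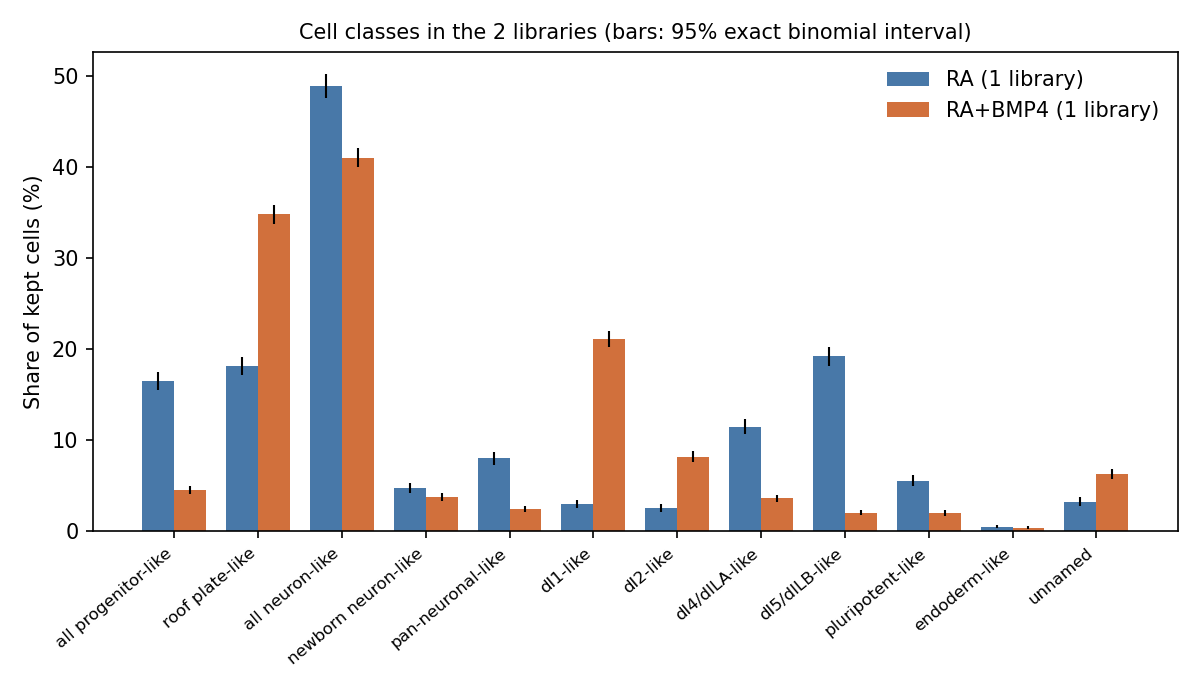
Share of kept cells (%) in each named class except mesenchyme-like, and in the unnamed clusters together, for the RA library (blue) and the RA+BMP4 library (orange). Bars show 95% exact binomial intervals. The bars for all neuron-like cells include the 6 neuron classes to their right, and dI1-like cells make up 2.97% and 21.1% of the libraries.

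The second comparison counted cells with a UMI of a domain marker, without clusters, after each cell was thinned to 5000 UMIs. The dI1 transcription factors Barhl1 and Barhl2 were found in 1.79% [1.46 to 2.16] and 1.33% [1.05 to 1.66] of RA cells and in 14.6% [13.8 to 15.4] and 15.5% [14.7 to 16.4] of RA+BMP4 cells. Atoh1 was found in 1.31% and 3.81%, Lhx2 in 1.26% and 3.90%, and Lhx9 in 0.963% and 5.18%. Foxd3, a dI2 factor that neural crest also expresses, was found in 1.47% and 5.21%, and Isl1, expressed by dI3 and peripheral sensory neurons, in 0.630% and 2.30%.

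Lbx1, which marks dI4 to dI6, was found in 14.2% of RA cells [13.3 to 15.1] and 2.82% of RA+BMP4 cells [2.46 to 3.21]. Tlx3, a selector of excitatory fate, was found in 15.9% and 9.05%, Pax2, a factor of inhibitory neurons, in 11.8% and 3.55%, and Lmx1b in 5.83% and 1.20%. The GABA-synthesising enzyme gene Gad2 was found in 8.07% and 2.88%, and Slc32a1, the vesicular GABA and glycine transporter, in 7.61% and 2.47%. Slc17a6, the vesicular glutamate transporter, was found in 506 of 5713 RA cells [8.13% to 9.62%] and in 1009 of 7778 RA+BMP4 cells [12.2% to 13.7%]. Olig3, a factor of the dorsalmost progenitors, was found in 3.03% and 10.2%, the latter above the 4.53% of RA+BMP4 cells named progenitor-like.

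Roof plate genes were found in more RA+BMP4 cells: Wnt1 in 8.38% and 25.6%, Rspo3 in 9.49% and 28.7%, and Msx1 in 16.6% and 36.2%. Dmrt3, a dI6 factor, was found in 1.16% and 0.167%, the latter beside 0.162% in cluster 1 of the same library. Shh, the floor plate ligand, was found in 0 RA cells, a count of 0 that allows a share of cells with a UMI of up to 0.0525%, and in 2 RA+BMP4 cells.

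Free RNA adds UMIs in cells that do not express a gene, so the shares in the mesenchyme-like cluster 1, which should lack the neural factors, are given as background. The median depths of its cells before thinning were 22049 UMIs in RA and 14331 in RA+BMP4. Barhl2 was found in 0 of 290 RA cells of cluster 1, which allows up to 1.03%, and in 1.46% of those of RA+BMP4. Barhl1 was found in 0.345% and 1.78%, Lbx1 in 2.07% and 1.13%, Pax2 in 0.345% and in 0 cells, which allows up to 0.485%, and Slc17a6 in 0.345% and 1.13%. Among the other transcription factor and transmitter genes above, Lmx1b excepted, the highest share in cluster 1 was 1.72%, that of Tlx3 in RA. The RA+BMP4 share of Lmx1b lay below its 1.94% in cluster 1 and is not read as neuronal. Rspo3 (6.55% and 14.2%) and Msx1 (4.14% and 9.39%) were frequent in cluster 1. The V1 markers En1 (7.91% and 13.6%) and Foxp2 (7.68% and 14.4%) lay below their shares in cluster 1, 13.1% and 23.8% for En1, so these genes alone do not identify V1 neurons here. Thinning left out 187 RA and 572 RA+BMP4 cells. Without it the shares were 2.19% and 20.3% for Barhl2, 24.5% and 4.26% for Lbx1, 17.4% and 4.63% for Pax2, 23.7% and 13.9% for Tlx3, 6.83% and 16.2% for Olig3, and 16.2% and 34.4% for Wnt1. They were 3.59% and 7.31% for Foxd3, 1.56% and 3.29% for Isl1 and 2.83% and 5.81% for Lhx2, ratios of 2.03, 2.11 and 2.05 in place of 3.54, 3.65 and 3.09. With at least 2 UMIs required, the ratio was 5.41 for Foxd3, 10.0 in place of 5.38 for Lhx9, and 0.373 in place of 0.569 for Tlx3. Of the genes named from these shares, Shh alone had the other order without thinning, at 0.153% and 0.0958%.

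**Figure D2:**
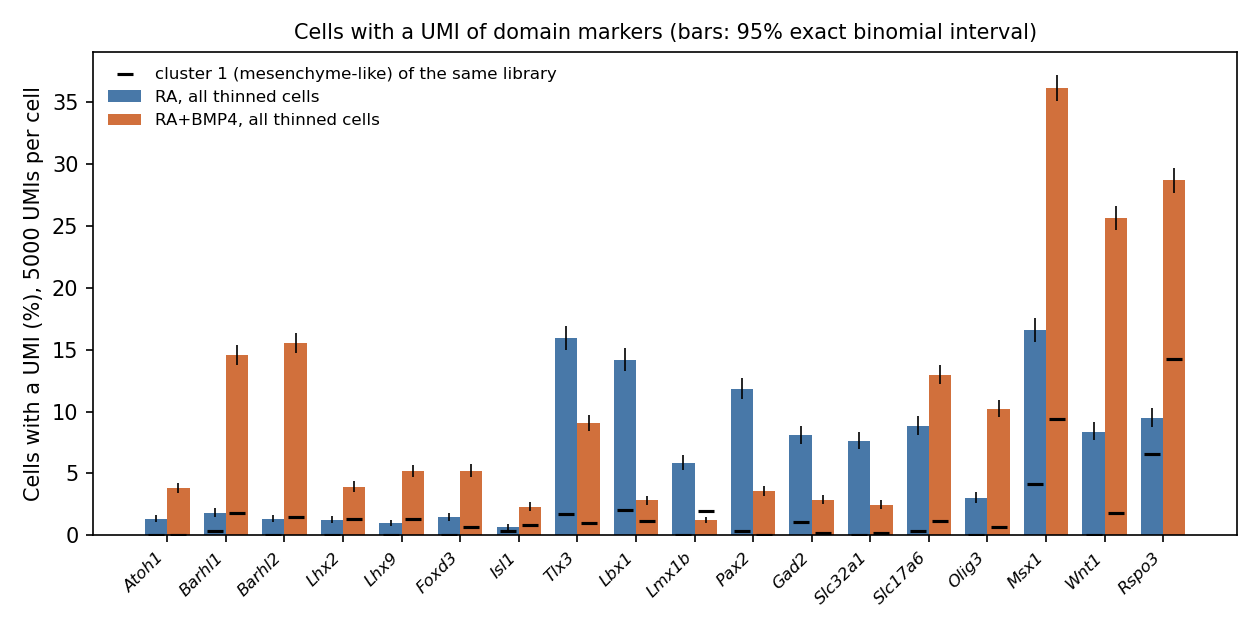
Share of cells (%) with at least 1 UMI of each marker gene after thinning to 5000 UMIs, in RA (blue) and RA+BMP4 (orange), with 95% exact binomial intervals as bars and the share among cells of the mesenchyme-like cluster 1 of the same library as black dashes. Barhl2 lies at 1.33% and 15.5%, and Lbx1 at 14.2% and 2.82%.

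The third comparison set summed counts of all kept cells side by side as CPM, the summed UMI counts scaled to a common total per library. Of 7152 genes with at least 20 CPM in 1 library, 60 were at least 2-fold higher and 43 at least 2-fold lower in RA+BMP4. With each cell weighted equally these numbers were 91 and 41, under the stricter cell filter 109 and 75, with TMM factors 52 and 46, and with median-of-ratios scaling 50 and 47. Without the pluripotent-like cells, an alternative added after the data were seen, 26 genes were lower. The dI1 homeobox gene Barhl2 (ENSMUSG00000034384, GRCm38 chromosome 5, 106452523 to 106458166) had the highest ratio, with 3.27 CPM in RA and 48.7 CPM in RA+BMP4, a log2 ratio of 3.90 [3.74 to 4.06]. Its paralog Barhl1 (chromosome 2, 28907679 to 28916668) had 5.06 and 46.7 CPM. The chemokine gene Cxcl14 had 3.68 and 21.7 CPM, the sorting receptor gene Sorcs3 7.63 and 41.4, the neurite outgrowth gene Nrn1 4.69 and 21.3, and Brinp2 8.60 and 30.3. AC154683.1, the contactin gene Cntn3 and the potassium channel gene Kcnn3 had log2 ratios of 1.81, 1.78 and 1.67. Hoxc9, a gene of thoracic identity on chromosome 15 (102976439 to 102985099), had 60.5 and 218 CPM, a log2 ratio of 1.85 [1.81 to 1.89].

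Among the 10 lowest ratios, Sox21 (chromosome 14, 118233232 to 118237030), a progenitor factor, had 22.1 and 3.45 CPM, a log2 ratio of -2.68 [-2.84 to -2.51]. Hopx had 23.0 and 4.27 CPM, Lbx1 26.6 and 5.77, Pax2 41.6 and 11.6, and the neuropeptide gene Cartpt 115 and 31.3. Lefty1, Tdgf1, Utf1, L1td1 and Lefty2, none of them in the fixed gene lists or markers, had log2 ratios of -1.92, -1.89, -1.83, -1.65 and -1.63. Between 91.2% and 97.4% of the counts of these 5 genes lay in the pluripotent-like cells in either library. Without those cells their log2 ratios were -1.02, -2.31, -1.83, -0.83 and -1.52, and they were no longer called because none reached 20 CPM, with at most 5.36.

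**Figure D3:**
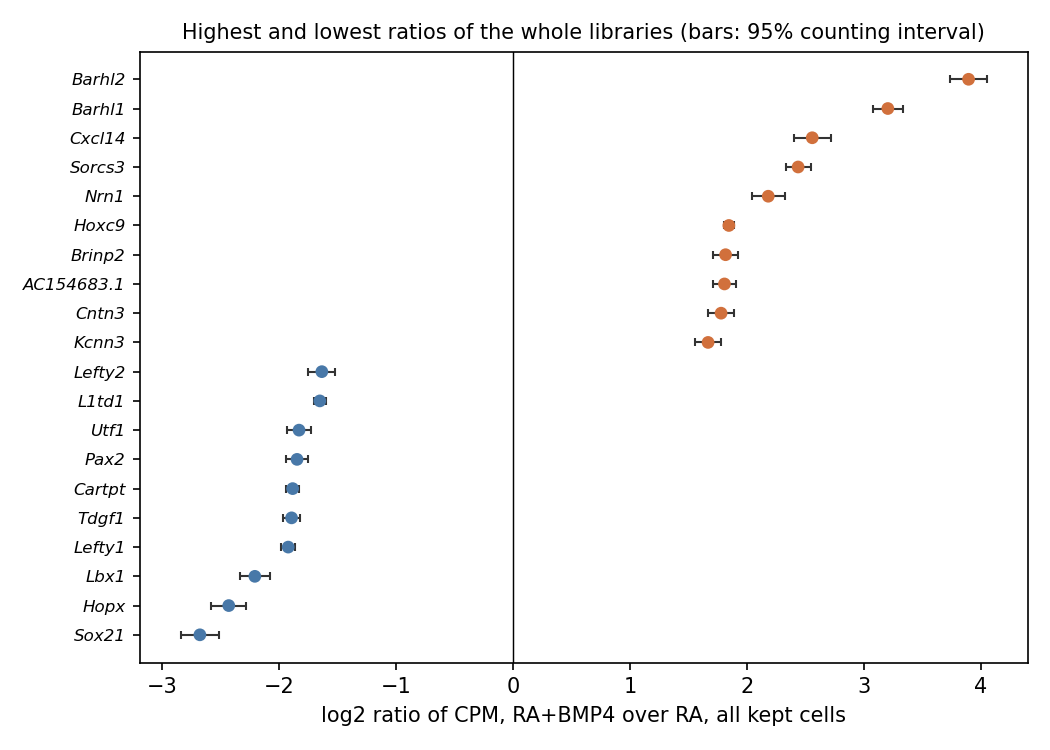
The 10 highest (orange) and 10 lowest (blue) log2 ratios of CPM, RA+BMP4 over RA, over all kept cells, with 95% counting intervals as bars. They run from 3.90 for Barhl2 to -2.68 for Sox21.

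Gene lists were compared with 10000 random lists matched on expression, as a description of these libraries. Of 19 lists with at least 3 measured members, 8 lay above the middle 95% of random lists and 5 below it. The BMP response list had a median log2 ratio of 0.46, with Id1 at 118 and 174 CPM, Msx1 at 99.7 and 206 and Msx2 at 5.14 and 16.9, while Id3 was 450.4 and 449. BMP ligands and inhibitors had a median of 0.44, with the roof plate ligand gene Gdf7 at 0.202 and 1.52 CPM and the activin inhibitor gene Fst at 12.9 and 3.61. Wnt targets (0.30) included Axin2 at 48.2 and 112 CPM and Ccnd1 at 123 and 73.6. Among Wnt ligands and R-spondins (0.47), Wnt1 had 28.0 and 86.7 CPM, Wnt3a 5.48 and 15.2 and Rspo3 39.7 and 125, while Wnt7b had 13.4 and 1.43 and Wnt7a 2.28 and 0.618. Retinoic acid pathway genes (0.49) included Crabp1 at 394 and 977 CPM and Rara at 71.7 and 121.

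Hox genes of paralog groups 9 to 13 had a median of 1.41 over 5 measured members. Hoxa9 had 24.8 and 66.2 CPM, Hoxb9 429.9 and 484, and Hoxa10 4.86 and 2.58. Groups 1 to 5 (0.12) and 6 to 8 (0.09) lay within the middle 95%. The commissural axon guidance list (0.43) included Robo2 at 31.3 and 81.9 CPM and Nrp2 at 90.0 and 163. The hypoxia and glycolysis list (0.52) included Bnip3 at 70.5 and 112 CPM and Ldha at 486 and 674, while Slc2a1 was 107 and 88.6.

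The GABAergic and glycinergic list had the lowest median, -1.21, with 4 of 6 members at least 2-fold lower, among them Gad1 at 6.55 and 2.79 CPM and the glycine transporter gene Slc6a5 at 6.02 and 2.26. Neuropeptides (-0.58) included Sst at 223 and 85.2 CPM, Tac1 at 2.53 and 0.657, and Npy at 6.24 and 13.2. S phase genes had a median of -0.45, G2 and M phase genes of -0.26 and Notch pathway genes of -0.20, the last with Hes5 at 41.5 and 16.6 CPM and Hes1 at 37.1 and 61.2. Medians for dissociation and heat stress (0.07), p53 response (0.10), cholesterol synthesis (0.03) and cytosolic ribosomal protein genes (-0.11) lay within the middle 95%. Leaving out the pluripotent-like cells changed several medians. S phase went to -0.28, G2 and M phase to -0.092 and Notch pathway to -0.30. Wnt targets went to 0.71, BMP response to 0.30 and commissural axon guidance to 0.28. All of these medians stayed outside the middle 95%, while the BMP ligands list, at 0.31, came to lie within it. Median-of-ratios scaling gave -0.34 for the Notch pathway. With each cell weighted equally, Wnt targets had 0.67, BMP ligands 0.75 and neuropeptides -0.33, and these too stayed outside it. The glutamatergic list had too few measured members for a median, and its main member Slc17a6 had 19.3 and 38.8 CPM.

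**Figure D4:**
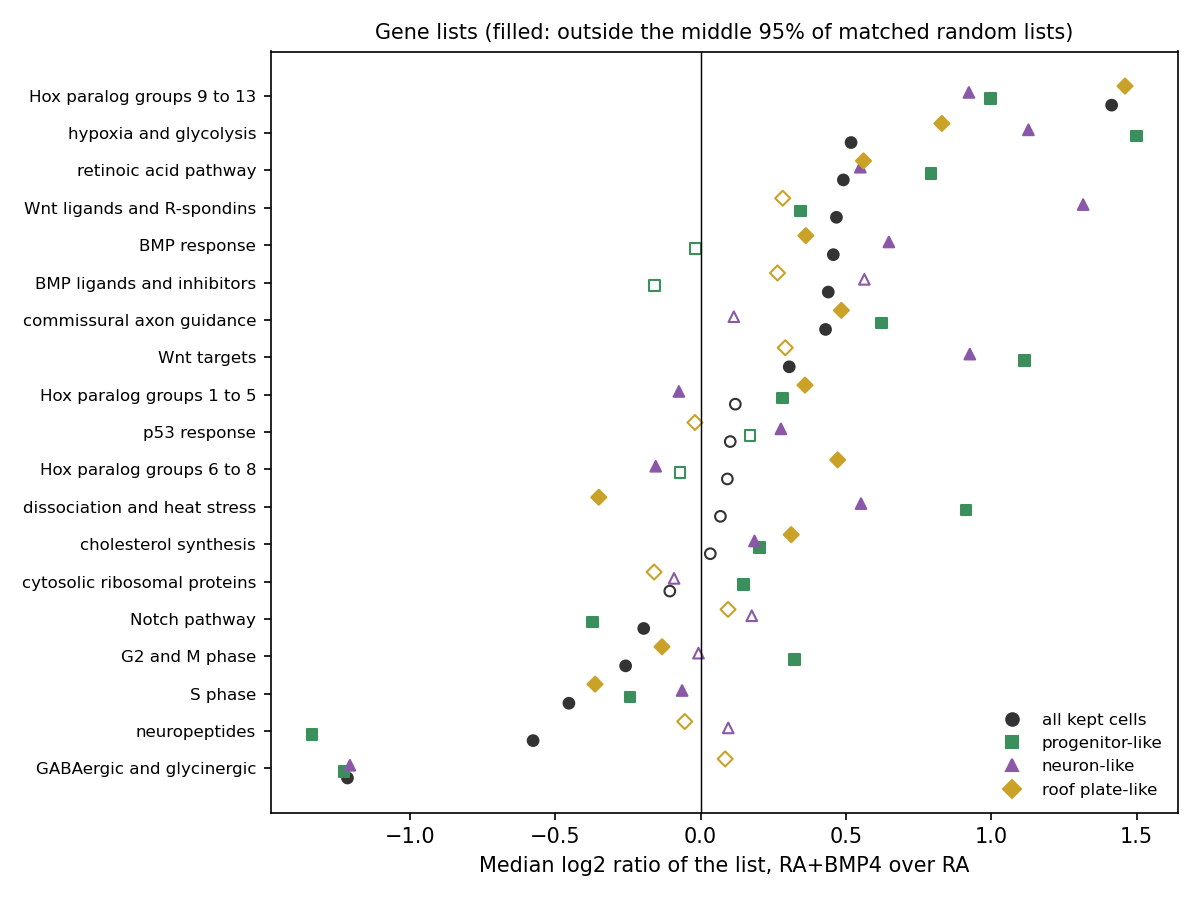
Median log2 ratio, RA+BMP4 over RA, of each gene list over all kept cells and within 3 cell groups, with filled symbols for medians outside the middle 95% of matched random lists. The hypoxia and glycolysis list lies at 0.52 over all cells, 1.13 in neuron-like and 0.83 in roof plate-like cells, and highest in progenitor-like cells.

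The comparison within progenitor-like cells set the level of a gene apart from the share of the class, but not from shares of progenitor domains inside it. With each library clustered alone, RA progenitor-like clusters were named neural progenitor or dP4 to dP6, and those of RA+BMP4 dP3. The ratios below can therefore also follow domain shares. Olig3 (chromosome 10, 19356533 to 19358604), which dorsal progenitors dP1 to dP3 express, had 1.39 CPM in RA and 23.0 CPM in RA+BMP4, a log2 ratio of 4.05 [3.38 to 4.78]. Atoh1 had 2 counts in RA and 52 in RA+BMP4, with a log2 ratio between 4.47 and 9.48. Neurog1, a proneural factor of dI2 progenitors, had a log2 ratio of 1.67 [1.41 to 1.94], while Gsx1 had a log2 ratio of -0.30 [-0.67 to 0.06]. The imprinted RNA H19 had 8.23 and 65.1 CPM, the lactate exporter gene Slc16a3 25.7 and 171, the glycolytic enzyme gene Pfkp 5.13 and 28.4, Ier3 4.62 and 25.9 and Prelid2 3.61 and 22.0. At the other end, Pdlim3 had 25.9 and 4.32 CPM, Wnt7b 76.8 and 17.1, the neuronal genes Cdk5r2 23.9 and 5.96 and Dab1 35.9 and 9.04, Hopx 138 and 36.8, and Nhs 24.4 and 6.78. Fabp7, a radial glial gene, had 6399 and 2839 CPM.

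Of 6689 genes, 77 were at least 2-fold higher and 45 lower, and median-of-ratios scaling gave 60 and 59. The lists above the middle 95% included hypoxia and glycolysis, with 8 of 10 members at least 2-fold higher, among them Pdk1 at 14.4 and 60.2 CPM. They also included Wnt targets (1.11), with Sp5 at 1.71 and 12.9, Hox groups 9 to 13 (1.00), dissociation and heat stress (0.91), retinoic acid pathway (0.79), commissural axon guidance (0.62) and Wnt ligands (0.34). G2 and M phase genes (0.32), Hox groups 1 to 5 (0.28), cholesterol synthesis (0.20) and ribosomal protein genes (0.15) also lay above it. Neuropeptides (-1.34), GABAergic and glycinergic genes (-1.23), Notch pathway (-0.37) and S phase genes (-0.24) lay below it. BMP response (-0.02), BMP ligands (-0.16) and p53 response (0.17) lay within it. The class held 971 RA and 378 RA+BMP4 cells.

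Within the 2883 RA and 3424 RA+BMP4 neuron-like cells, Barhl2 had 8.92 and 136 CPM, a log2 ratio of 3.93 [3.77 to 4.09], Barhl1 13.8 and 127, and Lhx9 4.92 and 46.2. Kctd4 (chromosome 14, 75955009 to 75966206) had 2.59 and 40.4 CPM, Cntn3 4.63 and 61.6 and the NMDA receptor gene Grin2a 3.52 and 31.8. Foxd3 had 9.08 and 40.7 CPM and Robo2 57.9 and 191. The lowest ratio was that of Lmx1b (chromosome 2, 33560965 to 33640511), with 27.1 and 3.74 CPM, a log2 ratio of -2.86 [-3.14 to -2.59]. The dI5 gene Prrxl1, also called Drgx, had 28.6 and 4.98 CPM, Lbx1 69.1 and 14.4, Cartpt 324 and 89.3, Pax2 112 and 32.4, and Irx2 33.9 and 9.91. Lhx1, shared by dI2 and dI4, had 256 and 249.5 CPM, and the general neuronal genes Tubb3 1905 and 2128 and Ina 949.8 and 963.

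Of 6958 genes, 105 were at least 2-fold higher and 32 lower. Median-of-ratios scaling, which shifted log2 ratios by -0.10, gave 85 and 45. Wnt ligands (1.32), hypoxia and glycolysis (1.13), Wnt targets (0.93), Hox groups 9 to 13 (0.92), BMP response (0.65), retinoic acid pathway (0.55), dissociation and heat stress (0.55), p53 response (0.28) and cholesterol synthesis (0.19) lay above the middle 95%. GABAergic and glycinergic genes (-1.21), Hox groups 6 to 8 (-0.15) and 1 to 5 (-0.07), and S phase genes (-0.06) lay below it. The 2 libraries filled this class with different clusters. RA cells lay mainly in clusters 2, 8 and 9, and RA+BMP4 cells mainly in clusters 4, 5 and 6. These ratios therefore follow subtype shares as well as levels within a subtype. Free RNA was not removed before the comparisons within classes, so it can add to their ratios too.

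Roof plate-like cells were compared as a further class, chosen after the data were seen. H19 (chromosome 7, 142575529 to 142578143) had 20.1 and 184 CPM, Slc16a3 7.99 and 70.6, Vstm2l 4.13 and 33.9, Olfm3 4.56 and 30.2, Ldb2 7.46 and 43.8, and the microfibril gene Mfap2 10.9 and 61.2. The Wnt antagonist gene Dkk2 had 29.7 and 7.51 CPM, Nhs 73.5 and 19.2, Shroom2 77.1 and 20.3, Trap1a 38.2 and 10.8, ceruloplasmin (Cp) 159 and 46.4, and the metallothionein gene Mt2 65.9 and 19.5. Wnt1 had 110.5 and 226 CPM, Msx2 11.7 and 39.8, Rspo1 87.0 and 74.8, and Lmx1a, a roof plate selector, 47.3 and 60.1. Of 7020 genes, 104 were at least 2-fold higher and 81 lower. The lists above the middle 95% were Hox groups 9 to 13 (1.46), hypoxia and glycolysis (0.83), retinoic acid pathway (0.56), commissural axon guidance (0.48), Hox groups 6 to 8 (0.47) and 1 to 5 (0.36), BMP response (0.36) and cholesterol synthesis (0.31). S phase (-0.36), dissociation and heat stress (-0.35) and G2 and M phase genes (-0.13) lay below it. Cluster 3 held 534 of the 1068 RA cells of the class and cluster 0 held 1856 of the 2903 RA+BMP4 cells, so genes that lead these clusters, such as Cp, also follow the cluster shares.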

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

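The tests on the hypoxia pattern were chosen after the result was seen. Their first form covered all 19 clusters with at least 50 cells in each library and gave a lowest median of -0.063 and a ratio of largest to smallest gain of -8.43, and they were then restated for neural clusters and for the smallest gain.

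Gene lists that lay on opposite sides of the middle 95% of random lists in different cell groups are given here as values, and the differences between groups were not tested. Hox paralog groups 1 to 5 had median log2 ratios of 0.28 in progenitor-like, 0.36 in roof plate-like and -0.074 in neuron-like cells. Hox groups 6 to 8 had 0.47 in roof plate-like and -0.15 in neuron-like cells. G2 and M phase genes had 0.32 in progenitor-like and -0.13 in roof plate-like cells. Dissociation and heat stress genes had 0.91 in progenitor-like, 0.55 in neuron-like and -0.35 in roof plate-like cells, with Fos at 18.9 and 44.8 CPM in progenitor-like cells and 282 and 109 CPM in roof plate-like cells of RA and RA+BMP4.

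The unnamed cluster 21, which entered no comparison of classes, held 2 RA cells and 122 RA+BMP4 cells, 1.46% of the RA+BMP4 library. Divided further, 59 of its cells (2 from RA) had Sox10 in 81.4% and the endothelial gene Cdh5 in 20.3%. Another 45, all from RA+BMP4, had Isl1 in 97.8% and Tlx3 in 91.1%, and the last 20 had Tlx3 in 55%.

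Hypoxia and glycolysis genes were higher in the neural clusters of the RA+BMP4 library, and also in cluster 19, led by muscle genes (median log2 ratio 0.85, gain 2.16 list UMIs per cell [1.61 to 2.71]). In the 14 neural clusters tested, the list median ran from 0.27 in cluster 3 to 1.78 in cluster 9. Clusters 6 and 16, with under 50 cells in 1 library, were left out. Mesenchyme-like clusters 1 and 15 and pluripotent-like cluster 14 had medians of 0.0096, 0.017 and -0.063. A different mix of clusters cannot raise the list inside a cluster, so it does not account for the neural medians. This follows from how the pattern was restated and is no separate test. The mix of cells inside a cluster was not tested. RNA shared by all droplets, as the only difference, is argued against by the gain per RA+BMP4 cell. It was 36.0 list UMIs [35.0 to 37.1] in cluster 7 but -4.27 [-6.29 to -2.26] in pluripotent-like cluster 14 and -3.43 in mesenchyme-like cluster 1. Clusters 14 and 1 had 3249 and 1180 CPM of the list in RA, so a fall in their own level could hide a gain from shared RNA. Culture or library differences other than BMP4 cannot be told apart from BMP4 itself, since there was 1 library per condition, and the mitochondrial share was lower in RA+BMP4 in 18 of the 19 clusters.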

How the results depend on the processing

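Alternatives without the pluripotent-like cells, without the unnamed clusters and with equal weight per cell for the lists were chosen after the data were seen. No paired analysis was possible because each condition had 1 library and the labels give no replicate numbers. Unless the setting itself shows it, the cause of a difference was not tested.

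Whole-library counts of 60 higher and 43 lower genes follow the limits set: 354 and 374 at a CPM of at least 1, 31 and 16 at 50, 224 and 128 at a ratio of 1.5, and 6 and 3 at a ratio of 4. At most 5% mitochondrial UMIs with at least 2000 genes gave 109 and 75, equal weight per cell gave 91 higher, and leaving out pluripotent-like cells gave 26 lower. A ratio of 1.5 gave 257 and 167 genes in progenitor-like cells and 275 and 90 in neuron-like cells.

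Of the ratios of class shares, that of neuron-like cells reversed to 1.10 under the stricter cell filter. That filter kept 1247 RA and 5894 RA+BMP4 cells. It also gave 0.311 for progenitor-like, 2.25 for roof plate-like, 16.6 for dI1-like, 5.25 for dI2-like and 0.130 for dI5/dILB-like cells. Without a cell filter the ratio was 0.310 for progenitor-like and 4.07 for dI2-like cells. A resolution of 0.6 gave 0.799 for neuron-like and 0.310 for progenitor-like cells, and 1.5 gave 0.529 for progenitor-like and 0.362 for dI4/dILA-like cells. With each library clustered alone the ratio was 0.314 for progenitor-like, 5.11 for dI1-like and 1.77 for dI2-like cells, and no RA+BMP4 cluster was named dI5/dILB-like, so that share had no value. Clustered alone, newborn neuron-like cells reversed to 1.30 and pan-neuronal-like cells to 4.39. The newborn neuron-like ratio was 0.400 without a filter, 0.933 under the stricter one and 0.956 with doublets kept. The pan-neuronal-like ratio was 0.401, 0.495 and 0.458 in these 3 settings, 0.207 with markers kept and 0.612 at a resolution of 1.5. That of endoderm-like cells, whose interval held 1, was 1.16 without a filter. Markers kept among the clustering genes gave 0.132 for dI5/dILB-like cells. The other 47 values of class ratios stayed within the 95% interval of the reported ratio.

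The numbers of lists outside the middle 95% stayed within 1.5-fold under all 4 alternatives, but the BMP ligands list went from percentile 99.3 to 94.9 without the pluripotent-like cells, and ribosomal protein genes from 20.6 to 1.73 without matching. Of the list medians, 70 values stayed within their interval and 6 moved, of the named gene ratios 41 and 19, and of the ratios of cells with a UMI 31 and 23. Of the 20 named whole-library genes, the 18 markers whose ratio of cells with a UMI was repeated and the lists outside the middle 95%, none changed sign. Genes named within classes were not repeated, and the other markers of the report only without thinning, where Shh had the other order. Lists within the middle 95% that changed sign were, without the pluripotent-like cells Hox groups 1 to 5 (-0.022) and 6 to 8 (-0.067) and ribosomal protein genes (0.027), with equal weight per cell Hox groups 6 to 8 (-0.072), and with median-of-ratios scaling dissociation and heat stress (-0.0055) and cholesterol synthesis (-0.040). Depth limits the shares of rare factors: Shh was found in at most 2 thinned cells of a library.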

Other observations

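The tests on genes of the pluripotent-like cells, on neuronal maturation and on depth in the dI1-like clusters were chosen after the result was seen, and that on the library explanation before it. The tests on these genes were replaced or redone once, and that on depth and the limits of the maturation test were restated more than once, after their values were known.

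Within the RA+BMP4 library, clusters 5 and 6 shared Barhl2 (327 and 294 CPM) but differed in other dI1 and axon guidance genes, all left out of the clustering genes. Lhx2 had 107 CPM in cluster 5 and 2.04 in cluster 6, Robo3, a receptor that lets commissural axons cross the midline, 433 and 31.4, Cntn2 371 and 68.1, and Pou4f1 73.4 and 9.74. Robo2, a Slit receptor, had 63.2 and 654 CPM, the growth cone gene Gap43 153 and 632, Sst 15.5 and 142, and Barhl1 199 and 302. Hox groups 1 to 5, 6 to 8 and 9 to 13 had median log2 ratios of -0.78, -0.61 and -1.48, cluster 6 over cluster 5. The dI1 marker list had -0.51 and neuropeptides had 1.97.

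The 2 clusters of dI1-like neurons may be subtypes, and this is a hypothesis. A difference between the libraries is argued against by clustering RA+BMP4 alone, which gave an adjusted Rand index of 0.681 with the 2 clusters, although most of cluster 6 was then named pan-neuronal-like rather than dI1-like. Depth, at medians of 9331 and 8509 UMIs, is argued against: of 141 markers and list genes left out of clustering, 29 were over 2-fold apart by intervals beyond 2-fold, 8 higher in cluster 6 and 21 lower, but at most 1 between the cells above and below the median depth of either cluster (11309.5 and 7492, 10629 and 6725 UMIs). The test planned earlier, clustering 1420 cells thinned to 5000 UMIs, did not decide it, with indices of 0.309, 0.414 and 0.540 at resolutions of 1, 0.6 and 0.3. A difference in neuronal maturation stays open, since the pan-neuronal list had a median of -0.021 while the newborn neuron list had -1.87; the first limits, set on the pan-neuronal list alone, would have excluded it and were widened because the newborn list goes with maturation.

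Of the 10 lowest whole-library ratios, 5 belonged to genes chosen here for a CPM at least 10-fold higher in the pluripotent-like cells than in all others (24.5-fold to 79.3-fold), outside the fixed markers, and no biological explanation was tested. The depth of the pluripotent-like cells is argued against: with each cell weighted equally, the median log2 ratio of the 5 genes was -1.92 [-2.23 to -1.59 over resampled cells], against -1.83 in summed counts, and 3 of the 5 still had 20 CPM in RA. Other classes add little to these whole-library ratios, since 91.2% to 97.4% of the counts of the 5 genes lay in the pluripotent-like cells. Those cells made up 5.51% of RA and 1.98% of RA+BMP4 cells. For the counts read in other classes, free RNA of the pluripotent-like cells cannot be told apart from low expression. Over 7 of these genes and the fixed pluripotent markers, counted in all 4 cell groups, the group medians spanned 0.51 [0.29 to 1.00 over resampled genes]. In the first version, with each group's own genes, the span was 1.01.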
